A study of Homo sapiens with 12 samples.

How the data were processed

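Expression was measured in 12 samples of BEAS-2B cells, 3 in each of 4 groups, on one-colour arrays, one array per sample. Groups and replicate numbers were taken from the sample titles. Labelling, hybridization and scanning were done by an array service, per the labels. Agilent Feature Extraction 11.0.1.1 gave the deposited spot intensity values, per the file headers. The processed intensity is background-subtracted and spatially detrended but not normalized between arrays, per the file headers. The deposited series table holds log2 values with the same median, 4.48, in every column. Set against the scanner files, its columns rose with slopes of 0.959 to 1.03 and correlations of at least 0.9925. Its scale is thus log2, with no centring of probes. Its sorted columns differed by a median of 5.57e-05 and at most 0.44, as quantile normalization gives. The tool used is not given in the sources used here. It served as an alternative, and 6 scanner probes were not in it.

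The log2 processed intensity of each array was reduced by its 75th percentile over non-control spots. Control spots were left out, as were 360 spots of 60 negative probes that the files do not code as controls. Spots marked as outliers, between 12 and 45 per array, were set to missing. Spots of one probe were averaged, which gave 60924 probes. Probes well above background on all 3 arrays of at least 1 group were kept, and 34598 were tested. The adjusted p threshold was 0.05 after Benjamini-Hochberg adjustment over all tested probes. Models were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 12 arrays in a 4-group fit that left 8 residual degrees of freedom. Log2 levels in the text are relative to the 75th percentile of the array.

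Arrays with the same scan stamp were taken as one slide, which gave slides of 8 and 4 arrays. The slide is thus defined by the scan. No separate record of the slide was used, so scan and slide cannot be told apart and are one block. The slide block was planned before the data were examined and left 7 residual degrees of freedom and 34576 tested probes. Only BaP lay on both slides. BaP replicate 3 has no partner of its group on its slide and adds nothing to the estimated spread of the blocked fit, in which it is assumed to vary like the other arrays. No 2 arrays held identical values. Same-numbered samples of different groups deviated from their group means with correlations of -0.284 to 0.277, above 0.1 in 3 of 18 pairs, so the numbers were not taken as pairs.

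The files name 60904 of the 60924 probes only by the maker's identifier, and no table that pairs these with genes was used here. The other 20 probes carry a RefSeq transcript and 10 spots each. All 20 matched a symbol through a table of assembly GRCh38.p14. The file headers name hg19, so no coordinates are given. GRM4 was too dim to test, and 2 of the named genes are not reported here, although their probes stayed in the fits. The rule for named genes was fixed before the data were examined. It took the largest changes past the threshold among genes with symbols, members of 19 gene lists, and 18 genes named whatever their result. None of the 18 was on a named probe. Of the 19 lists, covering AHR, NRF2, heat shock, p53, cell cycle, epithelial, mesenchymal, stem cell and SOCS genes among others, only hypoxia and glycolysis had named members, GAPDH and PGK1. The lists, the cell type markers and the alternatives that need gene names were therefore not analysed here. In their place all named genes were tested, and up to 2 probe identifiers per direction and comparison are printed. These had the largest called change among probes well above background on every array of both groups (all 4 groups for additivity) and, except for additivity, with no overlap of the group ranges. Probes not well above background in one group have only a bound, which can exceed the printed changes. This replacement was chosen after the data were seen.

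Alternatives fixed before the data were examined were quantile normalization, median centring, other filters on dim probes, outlier spots kept, fits of only the compared groups, an intensity trend with robust eBayes, array weights, the replicate number and the slide as blocks, the series table, a 2-fold minimum, and leaving out each array. The planned normexp correction needs a mean signal column that was not used here. Normexp on the median signal with an offset of 50 was added after seeing the data. Cyclic loess, the slide block with cyclic loess or quantile normalization, and the slide block without each array other than BaP replicate 3 were also added then.

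The models were tested on simulated data in which 67 probes each were changed 1.5-fold and 2-fold and 66 were changed 4-fold, out of 34598. For arsenic against vehicle, 46.3% of the 2-fold and 87.9% of the 4-fold changes were recovered, with 6 false calls. For departure from additivity 5.97% and 78.8% were recovered, with 7 false calls. For the combined exposure against vehicle a slide difference of the observed size (SD 0.786 on the log2 scale) was added. Without a slide term this gave 13664 false calls and recovered 92.4% of the 4-fold changes. With the slide as a block it gave 0 false calls and recovered 15.2%. The simulated noise was that of the fit with no slide term, which holds the gap between the BaP arrays. Far fewer probes were changed than were called in the real data, which makes the adjusted threshold stricter. The recoveries can therefore understate those in the real data.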

Results

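BEAS-2B is an established line of human bronchial epithelial cells. The study exposed it for 30 weeks to the DMSO vehicle, to 1 µM sodium arsenite (arsenic), to 2.5 µM benzo[a]pyrene (BaP), or to both agents together. Benzo[a]pyrene is a polycyclic aromatic hydrocarbon of smoke. Total RNA of 3 samples per group was hybridised to 12 one-colour (Cy3) arrays whose probes cover messenger RNAs and long noncoding RNAs. The labels do not say whether the 3 samples of a group were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. The background question of the study was how combined exposure relates to a cancer stem cell-like state.

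Between 51.4% and 61.7% of the 61104 spots of an array were well above background, and no spot was saturated. The number of arrays limits the precision. By their scan stamps the arrays were taken to lie on 2 slides. Slide 1 held 8 arrays, namely all vehicle and arsenic samples and BaP replicates 1 and 2. Slide 2 held 4 arrays, namely BaP replicate 3 and all samples of the combined exposure. Arrays of one group on one slide correlated across probes at r = 0.991 to 0.996. BaP replicate 3 correlated with the other BaP arrays at r = 0.971 to 0.973. Pairs of different groups on one slide reached 0.967 to 0.979, and pairs of different groups on different slides 0.940 to 0.964. Probes are not independent replicates. The first principal component held 51.0% of the variance and separated the slides. BaP replicate 3 had a score of 57.5 on it, against -39.9 and -43.9 for the other BaP arrays.

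**Figure D1:**
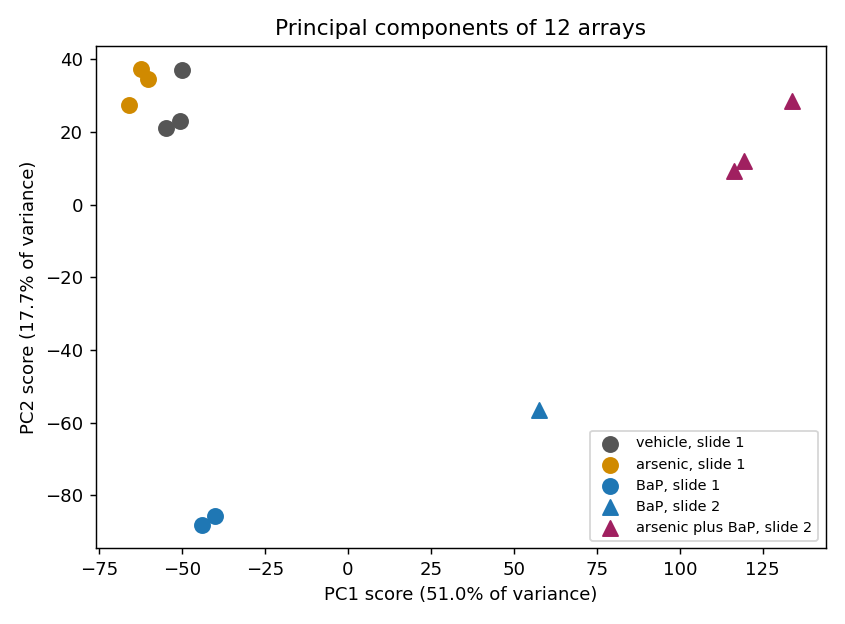
Scores of the 12 arrays on the first (horizontal) and second (vertical) principal component of the tested probes, coloured by exposure, with circles for slide 1 and triangles for slide 2. All 8 arrays of slide 1 lie below 0 on the first component, and the 4 arrays of slide 2 lie at 57.5 or above.

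Each comparison is therefore given in 2 forms, without a slide term and with the slide as a block. In the blocked fit, BaP against vehicle rests on BaP replicates 1 and 2 within slide 1. The combined exposure against BaP then rests on BaP replicate 3 within slide 2. The combined exposure shares no slide with vehicle or arsenic, so those blocked values rest on the single array BaP replicate 3 to join the slides. The files pair only 20 probes with a transcript name, and 17 of these genes are reported. They are mostly constitutively expressed genes. The other probes carry the maker's identifiers, of which a few are named for each comparison.

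Arsenic alone was compared with vehicle to ask what long exposure to arsenite changes. Both groups lay on slide 1, so the fold changes are those within 1 slide. Of 34598 probes tested, 1359 rose and 1992 fell, and 549 of the rises and 1349 of the falls were at least 2-fold. Probe ASHGV40040484 fell by 9.06 ± 0.23 (SE, n = 3) on the log2 scale, from 7.70 ± 0.28 (SD) to -1.36 ± 0.15, with a limma adjusted p of 3.56e-10. Probe ASHGV40011461 fell by 6.63 ± 0.32. Probes ASHGV40059866 and ASHGV40007540 rose by 5.51 ± 0.22 and 5.38 ± 0.23. None of the 17 named genes passed the threshold (limma), and 0 had an unadjusted p under 0.05. The value for MTX1, a protein of the mitochondrial outer membrane, was 0.36 ± 0.17, with an adjusted p of 0.252. GAPDH, a glycolytic enzyme, had 10.31 ± 0.15 (SD, n = 3) in vehicle and 10.52 ± 0.01 in arsenic, a difference of 0.21 ± 0.16 (SE) that did not pass. The control probes for human GAPDH are outside the tested probes. Of these Human-GAPDH_5 rose by 0.51 ± 0.12 (limma adjusted p = 0.0135, over the control probes). Human-GAPDH_3 had 0.24 ± 0.15 and passed only with the slide as a block (limma adjusted p = 0.0210). Control probes (+)E1A_r60_a22 and DCP_22_0, which are not for GAPDH, also rose, by 0.43 ± 0.11 and 0.44 ± 0.11. The other control probes not for GAPDH did not pass. The fold changes of this comparison were the same with the slide as a block, where the spread is estimated without the gap between the BaP arrays. There 7224 probes passed, 3790 up and 3434 down (3009 and 4196 with cyclic loess and the block), and 3348 of the 3351 calls kept their direction. MTX1 (0.36 ± 0.08) and ARHGDIA (0.27 ± 0.08) passed in that fit but not when cyclic loess or quantile normalization was used with the block. Both passed with array weights, and MTX1 also in a fit of only the 2 groups. Blocked fits were repeated without each array other than BaP replicate 3. ARHGDIA passed in 4 of these 11 fits, those without vehicle replicate 3 or a replicate of the combined exposure. Without BaP replicate 3 the count was 7232.

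BaP alone was compared with vehicle in the same way. With no slide term 2709 probes rose and 2435 fell. The balance turned with the scaling, since 2755 rose and 3255 fell with cyclic loess. ASHGV40007540 and ASHGV40007538 rose by 6.07 ± 0.23 and 6.07 ± 0.16 on the log2 scale (SE, n = 3). ASHGV40024060 fell by 5.47 ± 0.14 and ASHGV40007348 fell by 5.44 ± 0.25. Within slide 1 the rises were 5.79 ± 0.15 and 5.91 ± 0.12, and the values of the falling probes were -5.54 ± 0.13 and -5.78 ± 0.15. ASHGV40007540 therefore rose with either agent, from 2.55 ± 0.23 (SD) in vehicle to 7.93 ± 0.07 in arsenic and 8.62 ± 0.49 in BaP. None of the 17 named genes passed the threshold (limma), and 2 had an unadjusted p under 0.05. RPL10, a ribosomal protein gene, had -0.40 ± 0.14 (adjusted p = 0.0802). Its fall passed with cyclic loess, quantile normalization or normexp but not with the series table. With array weights, which gave BaP replicate 3 a weight of 0.0546, the 10 named genes that fell within slide 1 passed as well. Within slide 1, where the blocked fit compares BaP replicates 1 and 2 with vehicle, 11394 probes passed, 5448 up and 5946 down (6127 and 5862 with quantile normalization and the block). Of the 5144 calls without a slide term, 4991 were also called in the same direction there. Without BaP replicate 3 the count was 11387.

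Within slide 1, 10 of the 17 named genes had lower values in BaP past the threshold, and none had higher ones. H3-3A, which encodes a replication-independent histone H3, fell by 0.83 ± 0.12. EIF3D, a translation initiation factor subunit, fell by 0.73 ± 0.18. The ribosomal protein genes RPS18, RPLP1 and RPL10 fell, with values of -0.40 ± 0.13, -0.49 ± 0.15 and -0.46 ± 0.13. The RPL10 probe was far dimmer, at 0.12 in vehicle, against 10.48 for RPS18 and 10.41 for RPLP1. COX4I1, a subunit of cytochrome c oxidase, fell by 0.49 ± 0.13. Only H3-3A passed without any one of the 11 arrays other than BaP replicate 3. Of the 10 falls, 2 passed without BaP replicate 1, 2 without BaP replicate 2, 3 without vehicle replicate 3 and 5 without vehicle replicate 1. PRMT1 passed only without vehicle replicate 2 or combined exposure replicate 2. Most of these falls depended on the scaling. H3-3A, EIF3D and RPL10 passed also when the block was used with cyclic loess or with quantile normalization. The other 7 of the 10 did not pass with either. Of the 10 genes, 3 had values above 0 with cyclic loess and the block, and 2 with quantile normalization and the block.

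The combined exposure was compared with vehicle. Without a slide term 10075 probes rose and 6991 fell, which is 49.3% of those tested. Rises made up 59.0% of these calls, 50.5% with cyclic loess and 68.2% with normexp background correction. With the block 3785 rose and 3802 fell, and 4583 of the 17066 calls (26.9%) were called in the same direction, while 52 were called in the opposite one. ASHGV40047731 rose by 5.89 ± 0.15 on the log2 scale, and by 5.59 ± 0.21 in the blocked fit. It had 3.05 ± 0.13 (SD, n = 3) in the combined exposure and between -2.84 and -2.48 in the other 3 groups. ASHGV40053719 rose by 5.62 ± 0.19, or 6.04 ± 0.29 in the blocked fit. ASHGV40040963 fell by 5.98 ± 0.22 and ASHGV40007795 fell by 5.81 ± 0.17, with blocked values of -6.61 ± 0.31 and -6.41 ± 0.17.

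Of the named genes, 5 of 17 rose in that comparison without a slide term and 0 fell, while 1 rose and 1 fell with the block. MTX1 rose from 6.60 ± 0.03 (SD, n = 3) in vehicle to 7.70 ± 0.04 (limma adjusted p = 3.17e-04), and with the block it rose by 0.46 ± 0.14. It passed under every scaling tried, with and without the block, and without a slide term whichever array was left out. With the block the call was lost in 9 of the 11 fits that left out 1 array, with adjusted p up to 0.128, and passed only without combined exposure replicate 1 or 2. COX4I1 had 0.97 ± 0.22 without and 0.11 ± 0.22 with the block, but passed when quantile normalization was used with the block. PGK1, a glycolytic kinase, had 0.94 ± 0.17 without and 0.36 ± 0.18 with it. ODC1, an enzyme of polyamine synthesis, had 0.66 ± 0.22 without and -0.11 ± 0.26 with it. ARHGDIA had 0.50 ± 0.18 without and -0.23 ± 0.15 with it, and -0.072 with cyclic loess alone. H3-3A did not pass without the block (0.28 ± 0.26) and had -0.87 ± 0.19 with it, which passed. The blocked value contains the BaP effect of slide 1 by construction. For H3-3A that effect was -0.83 ± 0.12, and the difference within slide 2 was -0.041 ± 0.15. The call therefore carries over the lower value of BaP alone and is not separate evidence of a fall. It passed without any one of the 11 arrays other than BaP replicate 3, the array that joins the slides. Without that array no blocked value can be had, and H3-3A was called higher, by the same 0.28 as with no slide term. Of the 5 rises with no slide term, 3 passed with cyclic loess, with quantile normalization, with the series table or with no filter on dim probes. The rise of ODC1 was lost without vehicle replicate 1 or 2 or combined exposure replicate 2 or 3, and that of ARHGDIA passed only without a BaP array.

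**Figure D2:**
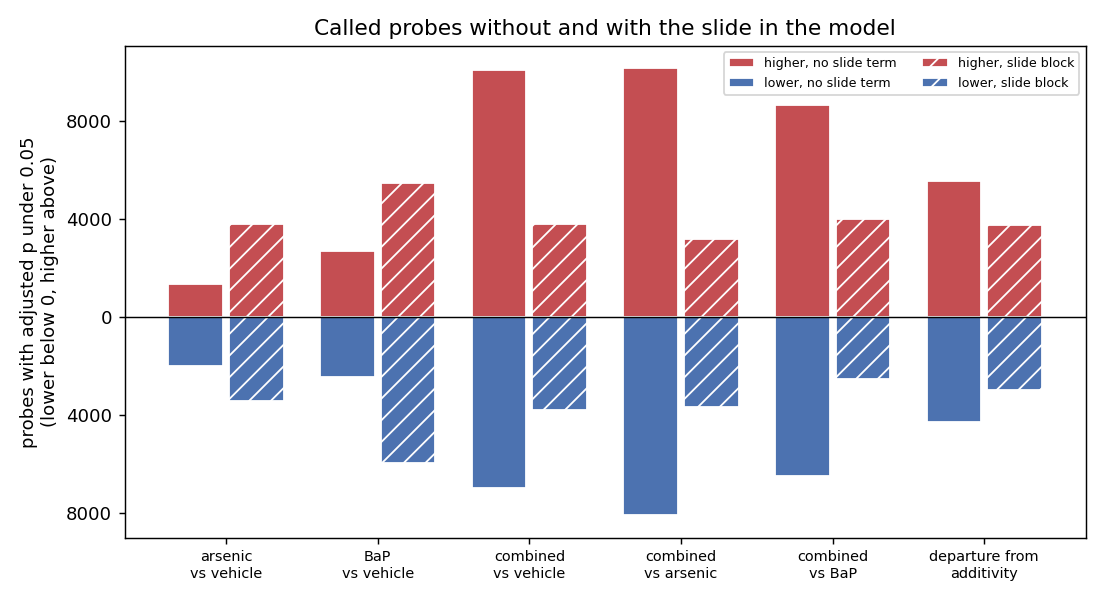
Number of probes with an adjusted p under 0.05, higher above 0 and lower below 0, for 6 comparisons (horizontal), without a slide term (plain bars) and with the slide as a block (hatched bars). Calls rise with the block for arsenic and BaP, from 3351 to 7224 and from 5144 to 11394, and drop in the comparisons of the combined exposure, from 17066 to 7587 against vehicle.

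Against arsenic alone, the combined exposure had 10143 probes up and 8090 down without a slide term, and 3196 up and 3667 down with it. These were 10513 and 5565 with normexp, and 3602 and 3543 with cyclic loess and the block. ASHGV40040484, which arsenic lowered, rose by 7.79 ± 0.23 on the log2 scale and reached 6.43 ± 0.20 (SD, n = 3) in the combined exposure, against 7.70 in vehicle. Its blocked value was 7.06 ± 0.30. ASHGV40037821 rose by 6.95 ± 0.23, or 6.07 ± 0.25 in the blocked fit. ASHGV40040500 fell by 6.06 ± 0.49 and ASHGV40034177 fell by 5.91 ± 0.52, with blocked values of -5.82 ± 0.95 and -4.70 ± 0.89. Of the named genes, 4 of 17 rose without a slide term, among them PGK1 (1.05 ± 0.17) and MTX1 (0.74 ± 0.17). None of these passed with the block, where ARHGDIA fell by 0.50 ± 0.15 and H3-3A fell by 0.62 ± 0.19. Of these 6 genes 1 was called higher with quantile normalization and the block, and 1 in the blocked fit without combined exposure replicate 1. Neither fall passed with cyclic loess or quantile normalization and the block, and each passed in 3 of the 11 blocked fits that left out 1 array. Those were without vehicle replicate 3 or combined exposure replicate 1 for both, without combined exposure replicate 2 for ARHGDIA and without vehicle replicate 2 for H3-3A. The rise of ODC1 (0.62 ± 0.22 without a slide term) was lost without arsenic replicate 1 or 2 or combined exposure replicate 2 or 3, with cyclic loess, and with no filter on dim probes. H3-3A (0.53 without a slide term) passed as a rise with array weights or only the 2 groups. Without BaP replicate 3 both H3-3A (0.53) and ARHGDIA (0.23) were called higher, so their direction rests on that array.

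Against BaP alone, 8661 probes rose and 6488 fell without a slide term. Within slide 2, against BaP replicate 3, 3988 rose and 2514 fell. With normexp background correction 67.9% of the calls without a slide term were rises, against 57.2% in the main setting. That correction also moved the median of all probes by 0.14 on the log2 scale here and by 0.15 for departure from additivity. ASHGV40005255 rose by 6.19 ± 0.19 on the log2 scale, and by 5.76 ± 0.17 within slide 2. ASHGV40043263 rose by 6.07 ± 0.54, or 5.61 ± 0.79 within slide 2. ASHGV40046297 fell by 5.75 ± 0.31 and ASHGV40053889 fell by 4.39 ± 0.24, with values of -6.61 ± 0.25 and -4.87 ± 0.27 within slide 2. Of the named genes 6 of 17 had higher values past the threshold without a slide term and 3 within slide 2. These 3 were COX4I1 (0.60 ± 0.17 within slide 2), MTX1 (0.58 ± 0.11) and PGK1 (0.61 ± 0.14). DYNLL1, a dynein light chain, had 0.54 ± 0.19 without a slide term, but -0.17 with cyclic loess. H3-3A had 0.72 ± 0.26 without a slide term and -0.041 ± 0.15 within slide 2. Of the 6 rises without a slide term, 3 passed with no filter on dim probes or only the 2 groups, and 4 with quantile normalization, median centring, cyclic loess or the series table. DYNLL1 was lost with the replicate block too. Of the 6, 3 passed without BaP replicate 1 or 2 or combined exposure replicate 2 or 3. RPL10 was lost in those 4 fits, H3-3A passed only without BaP replicate 3, and DYNLL1 only without that array or vehicle replicate 2. Within slide 2 COX4I1 was lost without vehicle replicate 1, BaP replicate 1 or 2, or combined exposure replicate 2, which left 2 genes. Without BaP replicate 3 the count of probes was 23180.

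**Figure D3:**
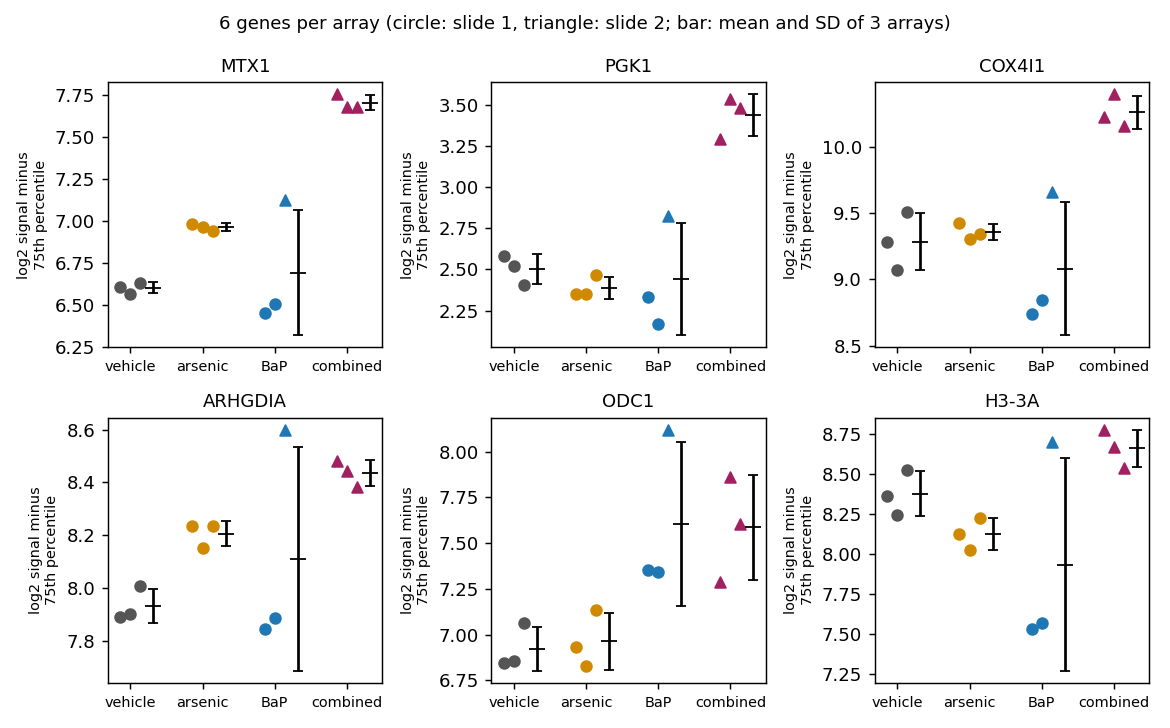
Normalised log2 signal of 6 named genes on each array (vertical) by exposure (horizontal), with circles for slide 1, triangles for slide 2, and a bar for the mean and SD of 3 arrays. In BaP, replicate 3 on slide 2 lies above the arrays of slide 1 for each of these genes, and the mean for MTX1 is 7.70 in the combined exposure and 6.60 in vehicle.

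Departure from additivity, the difference between the combined effect and the sum of the single effects, asks whether the agents act on a probe independently. Without a slide term 9858 probes departed, 5566 above and 4292 below the sum. In the blocked fit 6732 departed, 3765 above and 2967 below, of which 5162 were called in the same direction in both fits. In ASHGV40040484 the departure was 11.90 ± 0.32 on the log2 scale, or 11.41 ± 0.29 in the blocked fit. In ASHGV40037821 it was 9.64 ± 0.33, in ASHGV40007537 -9.34 ± 1.03 and in ASHGV40042140 -6.43 ± 0.30, with blocked values of 9.06 ± 0.24, -6.91 ± 0.29 and -6.96 ± 0.22. Of the named genes 3 of 17 departed upwards without a slide term. PGK1 had 1.11 ± 0.24 without and 0.72 ± 0.17 with the block and passed in both fits. It passed without any one of the 12 arrays in the fit with no slide term, and without any one of the 11 other than BaP replicate 3 in the blocked fit. The PGK1 probe lay at 2.50 in vehicle, below the control probe Human-PGK1_3 of the same gene at 8.34. Arsenic differed from vehicle by 0.11 for Human-PGK1_3 and by -0.11 for the PGK1 probe. Human-PGK1_3 had 9.06 in the combined exposure and 8.76 in BaP replicate 3, where the PGK1 probe had 3.44 and 2.83. The difference within slide 2 was thus smaller for Human-PGK1_3. Departure was not tested for the control probes, so that of PGK1 was seen only for the dimmer probe. RPL10 had 0.59 ± 0.20 without and 0.49 ± 0.20 with the block, at a level of 0.12 in vehicle, where RPS18 had 10.48. RPL10 passed only without BaP replicate 3 or combined exposure replicate 1, and COX4I1 was lost without vehicle replicate 3, arsenic replicate 2, BaP replicate 1 or 2, or combined exposure replicate 2. The count was thus 1 of 17 in each of those 5 fits. With no filter on dim probes only PGK1 passed of the 3, and RPL10 was lost with the replicate block. COX4I1 and RPL10 did not pass with the block alone, and COX4I1 passed when cyclic loess or quantile normalization was used with it. Without BaP replicate 3 the count of departures was 20925.

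The additivity contrast can also be read within slides, as arsenic minus vehicle on slide 1 against the combined exposure minus BaP replicate 3 on slide 2. These differences share no array. Across 34512 probes they correlated at Pearson's r = 0.0571, and the rank correlation (Spearman) was 0.0156. Of 236 probes changed at least 8-fold by arsenic alone, 129 (54.7%) had a difference in the same direction on top of BaP. The blocked fit called 91 of them in the same direction and 69 in the opposite one. Of the 52 rises 34 had the same direction, with 26 called so and 9 called opposite. Of the 184 falls 95 had the same direction, with 65 called so and 60 called opposite. In the direction of arsenic the median difference on top of BaP was 0.88 for the rises and 0.10 for the falls on the log2 scale. Among the 72 that were well above background on all 12 arrays, 33 had the same direction.

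**Figure D4:**
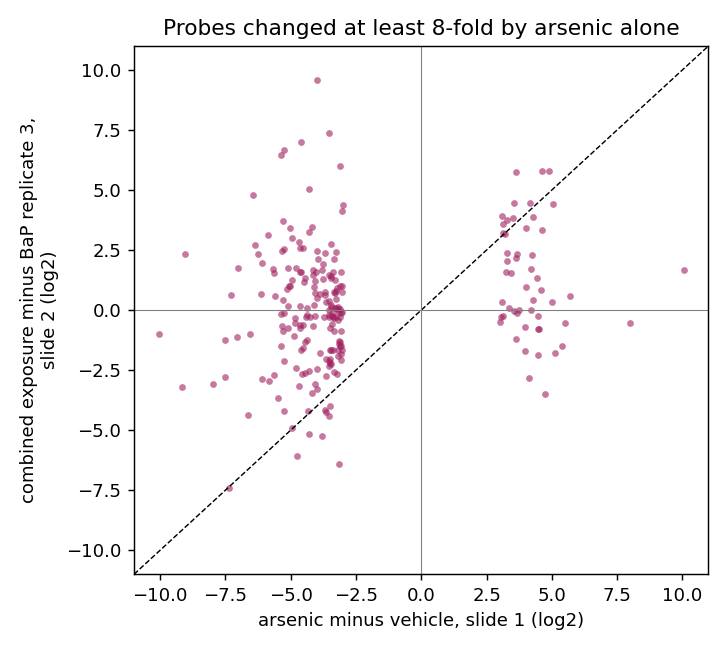
Log2 difference of arsenic minus vehicle on slide 1 (horizontal) against the combined exposure minus BaP replicate 3 on slide 2 (vertical) for 236 probes changed at least 8-fold by arsenic alone, one point per probe. The dashed line marks equal differences, and 129 of the points share their direction on both axes.

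Probes past the threshold against vehicle, arsenic and BaP in one direction were counted as beyond both single exposures. There were 5862 above and 3578 below without a slide term, and 1584 above and 953 below with it. With no slide term there were 4656 and 4029 with cyclic loess and 6286 and 2487 with normexp. Arsenic and BaP shared 466 rises and 931 falls, where independent lists would share 106 and 140, and 232 probes were called in opposite directions. Arsenic and the combined exposure shared 854 rises and 891 falls, against 396 and 403 in independent lists. BaP and the combined exposure shared 1740 rises and 1486 falls, against 789 and 492. Effects of unchanged groups, simulated in 20 draws against shared vehicle arrays, correlated at r = 0.50 across probes, and the observed correlations were 0.41, 0.25 and 0.52. The observed covariances were 0.180, 0.161 and 0.368, where the simulated ones were 0.031, 0.031 and 0.032. In the 20 draws 0 calls were shared for each pair. Unchanged groups rarely pass the adjusted threshold, so this 0 does not measure what shared controls add where groups do change. The simulation held no slide difference. BaP replicate 3 lies on slide 2 with the combined exposure. Part of the shared calls and of the covariance of BaP and the combined exposure may therefore come from the slide. The 3 vehicle arrays cannot be split into parts of at least 2, so part of the shared calls may come from the shared controls. In the blocked fit arsenic and BaP shared 1136 rises and 1866 falls, against 597 and 591 in independent lists. The blocked value of the combined exposure contains the BaP effect of slide 1 by construction. Its blocked overlaps are fixed in part by this and are not set against independent lists.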

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

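The tests of the slide difference on control probes, of RNA mixing and of the slide as the whole cause were chosen after the results were seen. The effect of arsenic differed with and without BaP in 9858 probes by the interaction term. Among named genes the interaction was 1.11 on the log2 scale for COX4I1, 0.59 for RPL10 and 1.11 for PGK1. Of these only PGK1 passed with the slide as a block alone.

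BaP replicate 3 stood apart from BaP replicates 1 and 2, with a median absolute difference of 0.567 on the log2 scale, against 0.116 to 0.212 for the arrays of the other groups. Mixing with RNA of the combined exposure is argued against, because probes at least 16-fold higher in that exposure had a median share of 1.14% in BaP replicate 3, while probes 4-fold to 8-fold higher had 20.3%. A signal-dependent scale difference is argued against as the whole cause, because with cyclic loess the difference was still 2.43 times the largest one of the other groups. A slide or hybridization difference is a candidate explanation. Of 17 control probes with no human target, 47.1% lay outside the range of slide 1 on all 4 arrays of slide 2. All 8 of these lay on the low side. Of the tested probes 37.6% lay outside it, 7421 above and 5542 below. Free exchange of the arrays gives 0.404%. But slide 2 held only BaP replicate 3 and the combined exposure, so an exposure effect can separate the slides too. Within slide 1, BaP differed from vehicle by -0.96 for DCP_1_4, -1.16 for DCP_1_7 and -0.43 for ERCC-00043_129, all among the 8. ERCC-00062_278, Rat-GAPDH_3 and Mouse-GAPDH_5 went the other way, by 1.58, 0.57 and 0.082. The shares therefore do not tell slide from exposure. The control probes can also bind human transcripts, so a different state of the BaP replicate 3 culture stays open, untested.

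The combined exposure differed from vehicle in 17066 probes, and it may differ by slide alone in many of them. With the slide as a block 7587 probes passed, and at least 4778 did when any array other than BaP replicate 3 was left out. Whether the slide is the whole cause cannot be told apart from the exposure, since that value rests on a single joining array. Of the calls the block ended, 94.6% moved the same way in BaP replicate 3, but the block is built from that difference, so this test decides nothing. A biological effect of the combined exposure stays open.

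The response to arsenic alone recurred only in part on top of BaP, where the blocked fit called 91 of 236 probes in the same direction and 69 in the opposite one. Array noise in BaP replicate 3 is not excluded. Only 54.7% of the probes changed at least 8-fold by arsenic moved in the same direction, fewer than set beforehand for noise. But BaP alone called 157 of the 236 in the arsenic direction, and where little change remains, noise can set the sign. BaP having already moved these probes stays open. Of those with no difference in that direction, 74.8% were called in the arsenic direction by BaP alone, against 157 of all 236. The 74.8% lies between the bounds set beforehand for and against that explanation. A culture of BaP replicate 3 that was not typical of its group, and a biological interaction of the agents, also stay open and untested.

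Splits of 3 against 3 arrays number 10, too few for a share under 0.05, and only 1 split of each, the real one, reached its count. Real counts and the highest other split were 3351 and 2 for arsenic, 5144 and 0 for BaP, 17066 and 0 for the combined exposure, 18233 and 0 for it against arsenic, and 15149 and 3 for it against BaP. For additivity 1 of 100 splits of the 12 arrays, the real one, reached 9858, and the highest other gave 4909. For probes beyond both exposures 1 of 100 reached 9440, and the highest other gave 2. For the overlap of arsenic and the combined exposure 1 of 100 reached 1745, and the highest other gave 131. For the overlaps of arsenic with BaP (1397) and of BaP with the combined exposure (3226), 2 of 100 reached the real value, with 4274 and 4649 in the highest other. Free exchange of the arrays is excluded at 0.05 for these 5 results. But the other splits mix arrays of different groups, which adds the group differences to their spread. Any group difference can therefore favour the real grouping, so the splits do not bear on additivity or overlap as such. The samples of a group may share a culture, so chance differences between cultures are not excluded. The splits exchange arrays across the slides while the real groups follow them, so they exclude nothing about the slide. Both higher splits put BaP replicate 3 and combined exposure replicates 1 and 2, all from slide 2, in the place of vehicle, so they follow the slide. The blocked overlap of arsenic with BaP was 3002, and that of BaP with the combined exposure is fixed in part by the construction of the block.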

How the results depend on the processing

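Cyclic loess, normexp on the median signal, the slide block with cyclic loess or quantile normalization, and the slide block without each array other than BaP replicate 3 were tests chosen after the results were seen. The cause was not tested for the changes below, except that a 2-fold minimum can only lower a count. Results are given in the order arsenic, BaP and the combined exposure against vehicle, the combined exposure against arsenic and against BaP, departure from additivity, probes beyond both single exposures, and the overlaps of arsenic with BaP, of arsenic with the combined exposure and of BaP with the combined exposure.

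With the slide as a block the counts were 7224, 11394, 7587, 6863 and 6502, then 2537 beyond both exposures and 3002 shared by arsenic and BaP. With cyclic loess and the block they were 7205, 11122, 7939, 7145 and 6903, then 2757 beyond both, and overlaps of 3152 and 2667 for arsenic. With quantile normalization and the block they were 7557, 11989, 8006, 7035 and 6615, then 2605 beyond both, and overlaps of 3311 and 2717 for arsenic. The blocked overlaps of arsenic with the combined exposure, 2667 and 2717, are fixed in part by the construction of the block. Array weights gave 10690 for arsenic, 19628 for BaP, 25051 against BaP, 23044 for additivity, 15758 beyond both, and overlaps of 5470, 4966 and 7207. The weight of BaP replicate 3 was 0.0546. Fits of only the 2 groups compared gave 7001 for arsenic, 2716 for BaP and 6402 against BaP. A 2-fold minimum gave 1898, 2338, 7585, 8121 and 5765, then 3002 beyond both, and overlaps of 786, 912 and 1235. Without a filter on dim probes 5957 departed from additivity and BaP shared 2132 calls with the combined exposure. Of the counts, 230 values over all settings were within 1.5 times the value given in the report and 155 were not.

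Leaving out 1 array, with or without the slide block, gave ranges of 2157 to 7889, 2832 to 12415, 4778 to 21794, 4182 to 22655, 5601 to 23180, 5234 to 20925, 1608 to 15473, 930 to 3359, 1179 to 3685 and 1799 to 5056. The top of the last range is a blocked overlap, fixed in part by the construction of the block. It was 4255 without a slide term. Without a slide term, the arrays that moved a count by over 1.5 times were these. Leaving out BaP replicate 3 gave 7232 for arsenic, 11387 for BaP, 23180 against BaP, 20925 for additivity, 15473 beyond both, and overlaps of 3001 and 3685 for arsenic. Vehicle replicate 1 gave 2157 for arsenic, 3395 for BaP, and overlaps of 930 and 2118 for arsenic with BaP and BaP with the combined exposure. Vehicle replicate 3 gave 2832 for BaP and an overlap of 1799. Arsenic replicate 2 gave 2207 for arsenic and 6307 for additivity. BaP replicates 1 and 2 gave 8721 and 8529 against BaP, 6265 and 6195 for additivity, and 5961 and 5922 beyond both. Combined exposure replicate 2 gave 9639 against BaP, 6424 for additivity and 5868 beyond both. A group left with a single array on a slide is assumed to vary like the others.

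Single log2 values kept their direction and their side of the threshold in 1720 cases, passed only in the alternative in 141, missed the threshold in 218 and turned in 77. With the slide as a block ODC1 had -0.11 against vehicle and -0.15 against arsenic, ARHGDIA -0.23 and -0.50, and H3-3A -0.87, -0.62 and, against BaP, -0.041. With cyclic loess and the block ARHGDIA had -0.024 against vehicle, H3-3A -0.66 against vehicle and -0.13 against BaP, and DYNLL1 -0.039 against BaP. With quantile normalization and the block H3-3A had -0.55 against vehicle and -0.042 against BaP. With cyclic loess alone DYNLL1 had -0.17 against BaP and ARHGDIA -0.072 against vehicle. Over the leave-one-out fits with and without the block the ranges were -0.00081 to 1.08 and -0.031 to 0.95 for COX4I1 against vehicle and against arsenic, -0.25 to 0.81 and -0.29 to 0.77 for ODC1, -0.25 to 0.54 and -0.53 to 0.26 for ARHGDIA, and -0.93 to 0.36 and -0.67 to 0.59 for H3-3A. H3-3A against BaP ranged from -0.098 to 1.11.

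The replicate number as a block gave 2903, 4394, 16369, 17585, 14269, 8978, 8814, 1207, 1539 and 2701, each within 1.5 times the count without it. The numbers did not pair the samples, since 3 of 18 same-numbered pairs deviated together above r = 0.1 and 3 of 12 arrays correlated best with an array of their own number. Weak signal may limit the rest, which was not tested: between 51.4% and 61.7% of the spots of an array were well above background. The alternatives that need gene names or a mean signal column were not run.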

Other observations

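The response classes and the control probes were examined after the results were seen. Some probes were not well above background on any array of one group, so their changes are lower bounds. Against vehicle, 45 of 75 such probes in arsenic passed the threshold and were at least 2-fold higher by their bound. Likewise 183 of 492 passed and were at least 2-fold lower. For BaP these were 59 of 152 and 187 of 345, and for the combined exposure 270 of 352 and 294 of 890. The largest bounds among probes that passed were at least 222-fold higher and 314-fold lower in arsenic. They were 162-fold and 342-fold in BaP, and 109.6-fold and 288-fold in the combined exposure. Against arsenic alone the combined exposure reached at least 558-fold higher. The bound set the bright mean against the higher of the lowest signal well above background and the signal of the dim probe on each array. The values for the combined exposure carry no slide term.

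Of 17066 probes called in the combined exposure without a slide term, 72.8% were called with neither agent alone. With the slide as a block this share was 27.0% of 7587 probes. The share without a slide term carries any slide difference, and the blocked share is fixed in part by the construction of the block. All 3 exposures changed 1004 probes in one direction without a slide term, 384 up and 620 down. With the block there were 1676, 538 up and 1138 down, with the same limit of construction.

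In arsenic against vehicle, all on slide 1, each of the 6 control probes for GAPDH was higher on every arsenic array than on any vehicle array. The log2 difference was 0.51 ± 0.12 (SE) for Human-GAPDH_5, 0.24 ± 0.15 for Human-GAPDH_3, 0.53 ± 0.12 for Rat-GAPDH_5, 0.29 ± 0.30 for Rat-GAPDH_3, 0.49 ± 0.15 for Mouse-GAPDH_3 and 0.22 ± 0.15 for Mouse-GAPDH_5. In the fit with no slide term Human-GAPDH_5, Rat-GAPDH_5 and Mouse-GAPDH_3 passed (limma, adjusted over the control probes), with adjusted p of 0.0135, 0.0135 and 0.0360. The other GAPDH probes did not pass in that fit. With the slide as a block, all 6 GAPDH probes passed, with limma adjusted p from 5.84e-04 to 0.0210. A rise was not particular to GAPDH. Control probes (+)E1A_r60_a22 and DCP_22_0, which are not for GAPDH, passed too in both fits, at 0.43 ± 0.11 and 0.44 ± 0.11 with no slide term. Their log2 levels in vehicle were low, at -3.45 and -3.55. Each was higher on every arsenic array than on any vehicle array. The remaining control probes did not pass, with differences of either sign.

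One control probe for PGK1, Mouse-PGK1_3, was lower on slide 2. Its log2 level was 3.86 on slide 1, 2.37 in BaP replicate 3 and 2.76 in the combined exposure. The other PGK1 control probes had higher mean levels there. In arsenic plus BaP against vehicle without a slide term the difference was -1.12 ± 0.29 (SE) for Mouse-PGK1_3, 0.85 ± 0.28 for Mouse-PGK1_5, 0.87 ± 0.27 for Rat-PGK1_5, 0.72 ± 0.18 for Human-PGK1_3 and 0.91 ± 0.29 for Human-PGK1_5.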
